A study of Mus musculus with 16 samples.

How the data were processed

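RNA was counted in nuclei of the hippocampus of 8-week-old male C57BL/6J mice whose tissue had been held at 25 °C for 0, 24, 36, 48 or 54 h and then snap frozen, with 3 libraries per time point and 4 at 54 h. Per the labels, nuclei were sorted, run on the 10x Chromium 3' version 3 chemistry and sequenced on a NovaSeq 6000. The labels give 3 mice per group and do not say how the 4 libraries of 54 h relate to them, so each library was taken as 1 replicate. The deposited values are UMI counts per gene and barcode, made with Cell Ranger 5.0.1 per the file headers and aligned to mm10 per the submitters' processing notes. Those notes also name Seurat 4.0, and its use is not given in the sources used here, nor are the annotation release, the strand counted and whether intronic reads were counted. No barcode held fewer than 500 UMIs, so the matrices are filtered ones. Each matrix lists 32285 genes, of which 32158 have their identifier in the GENCODE vM21 annotation used here for coordinates and gene spans. Total UMIs per library ran from 32506418 to 106038520.

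Nuclei were kept with at least 500 genes, at most 5% mitochondrial UMIs and no doublet call of Scrublet, which was run per library in scanpy 1.11.5. Scrublet called under 0.5% of barcodes in 10 libraries (24 h replicate 3, all of 36 h and 54 h, 48 h replicates 1 and 2) and is taken not to have worked there. Kept nuclei numbered 2991 to 14076 per library, 123668 in all. Barcodes with at least 200 genes were scaled to 10000 counts, logged and clustered on 3000 variable genes, 40 principal components and 15 neighbours with Leiden at resolution 1 (leidenalg 0.10.2), with no correction between libraries. Of 61 clusters with 50 or more nuclei, 45 were named by fixed markers, at least 3 of which had to be detected in 10% of the nuclei at 2-fold the level of other clusters. Clusters with over 20% doublets stayed unnamed, as did those at UMI counts under 1/3 of their libraries' without a marker among their top 10 genes and those with more markers of another type in that top 10. The 17 classes named this way are labels by marker and were not checked against another source.

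Counts were summed over nuclei per library, and libraries, not nuclei, are the replicates. The test was edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr) in R 4.3.3, in 1 fit of all 16 libraries with 5 time points and 11 residual degrees of freedom, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are the log2 fold change over the root of F. Class sums were tested in 12 classes, where at least 2 libraries per time point held 20 or more of the nuclei, and smaller sums were left out. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, which assumes nearly independent members, with an estimated correlation and fry beside it. The 22 lists and 21 sets of markers, the comparisons, tests and filters were fixed before the data were examined. A rise or fall is stated where the adjusted p was under 0.05, and other values are given without a direction. The words highest, lowest and most refer to the genes that the text names, not every gene the rule picks, among genes with more than 3 UMIs in each group, and at every step some genes whose call ended without 1 library are left out, a choice made after these values were seen.

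By a rule fixed beforehand, the text names for all nuclei the 8 genes with the largest and the 8 with the smallest log2 fold change past the threshold, with a mean of at least 20 CPM and no overlap between the libraries compared, and for classes the 4 and 4 with at least 50 CPM. Unnamed gene models are named where a fixed list holds them. The 3 members of each list with the smallest p could also be named, and the 2 most abundant markers of each type. A gene without a UMI in a group is given as at least N-fold, against a floor of 3 counts over the group, and with 1 to 3 UMIs as a ratio of UMI shares with its 95% counting interval. These floors and intervals cover counting error alone, not the spread between libraries. Shares of classes and quality values were tested by the slope on hours (100000 permutations, two-sided) and by exact two-sided permutation tests of single times.

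On simulated data with the means and spread of all nuclei, 54 h against 0 h, edgeR called 20%, 58%, 96% and 98% of genes changed 1.5-, 2-, 4- and 8-fold, and 4.90% of its calls were false, against 24.6% for DESeq2 1.42.0. In dentate granule cells it called 86% at 2-fold, in microglia 6% at 2-fold and 80% at 8-fold. The alternatives were DESeq2's size factors, its Wald test, other filters of genes and nuclei, doublets kept, thinned sums, the replicate number as a block, the 2 times compared alone, sums weighted to 1 composition, coarser clusters and each library left out. Another 4 alternatives, named below, and the 4 pairs of classes tested for a difference were chosen after seeing the data. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.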

Results

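RNA of single nuclei was counted in 10x Genomics droplet libraries from the hippocampus of 8-week-old male C57BL/6J mice. After death the dissected tissue was held at 25 °C for 0, 24, 36, 48 or 54 h, then snap frozen and kept at -80 °C. The 0 h tissue was frozen at once and is the control of each comparison but 1, that of 54 h with 24 h. There were 3 libraries each at 0, 24, 36 and 48 h and 4 at 54 h. Of 149559 barcodes, 123668 nuclei were kept and 101573 fell into 17 classes of cells named by fixed markers. The question asked of each comparison is what storage at 25 °C did to the yield of nuclei, to the classes recovered and to their transcripts.

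Fewer nuclear barcodes were recovered the longer the tissue had been stored. The number of barcodes averaged 15017 ± 5073 at 0 h, 10865 ± 4190.2 at 24 h, 8779 ± 4025 at 36 h, 7099 ± 413 at 48 h (SD, n = 3 each) and 6069.8 ± 3893 at 54 h (SD, n = 4). The slope over the 16 libraries was -1649 barcodes per 10 h (two-sided permutation test, p = 0.00229, adjusted p = 0.011 over 5 measures). Without 0 h replicate 1 it was -1198 per 10 h with an adjusted p of 0.085, so this call rests on that library. Exact permutation p values against 0 h were 0.1 at 48 h, the smallest that 3 against 3 allows, and 0.0857 at 54 h. Median UMIs per barcode were 2998 ± 579 at 0 h, 6530 ± 2157 at 24 h, 3673 ± 2004 at 36 h, 5999 ± 3056 at 48 h and 5682 ± 2714 at 54 h (slope 414 per 10 h, permutation test, adjusted p = 0.27). This slope passed in kept nuclei alone (783, adjusted p = 0.041), with means (933, adjusted p = 0.0059) and without all replicate 1 libraries (606, adjusted p = 0.043, range 0.0059 to 0.43 over all alternatives). In 1000 UMIs drawn per barcode, 671 ± 7.66 genes were seen at 0 h and 703 ± 17.5 at 54 h (slope 5.66, adjusted p = 0.21, permutation test), which passed in kept nuclei alone (6.97, adjusted p = 0.043) and without all replicate 1 libraries (9.09, adjusted p = 0.013, range 0.013 to 0.91). Transcripts of the mitochondrial genome had a median of 2.804% of UMIs in 0 h replicate 1, 0 and 0.0141% in replicates 2 and 3 and 0.125 to 2.31% in the stored libraries. The slope was -0.0188 (permutation test, adjusted p = 0.88), 0.143 without 0 h replicate 1 (adjusted p = 0.20) and 0.352 with means in place of medians (adjusted p = 0.043, range 0.043 to 0.98 over all alternatives).

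**Figure D1:**
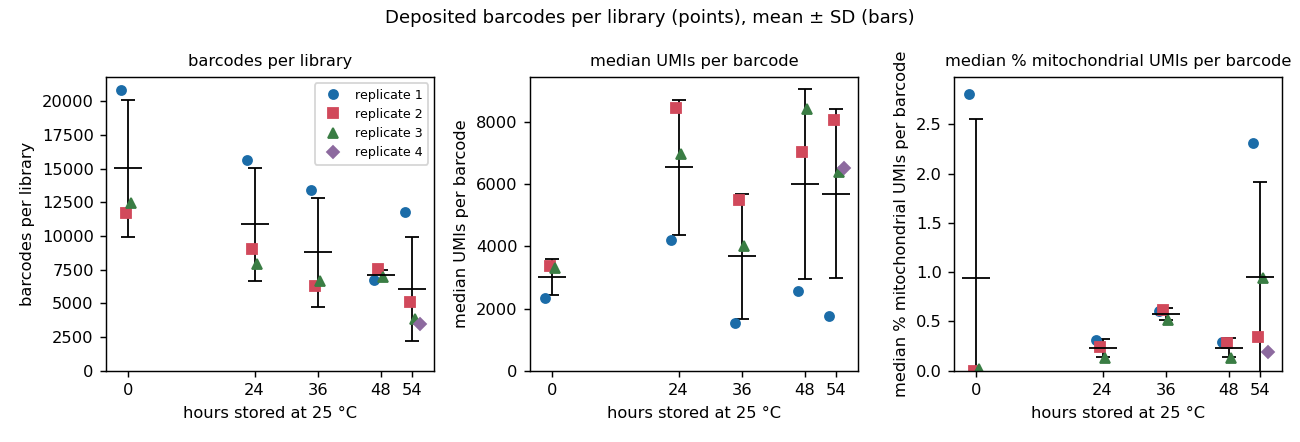
Barcodes, median UMIs and median percent of mitochondrial UMIs per library (vertical axes) by hours at 25 °C (horizontal axis), each point a library and bars the mean ± SD. The number of barcodes averaged 15017 at 0 h and 6069.8 at 54 h.

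One control library stood apart from the others of its time point. In 0 h replicate 1 the lowest total of a barcode was 1166 UMIs, against 500 to 562 in the other 15 libraries, and 28.6% of barcodes held over 5% mitochondrial UMIs. That share was 27.7% in 54 h replicate 1 and at most 20.1% in any other library. Few nuclei of 0 h replicate 1 were named as excitatory neurons, 15 as CA1 and 21 as CA3 pyramidal cells, while 0 h replicates 2 and 3 held 1084 and 1511 CA1 nuclei. The controls of dentate granule and CA1 cells therefore come from 0 h replicates 2 and 3 alone. An unnamed cluster with Camk2a and Grin2a among its top 10 genes held 36.6% of the kept nuclei of 0 h replicate 1, which the shares of named nuclei leave out.

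Cells of the oligodendrocyte line, which make the myelin of the brain, took a shrinking share of the nuclei. Oligodendrocytes were 16.9 ± 7.14% of named nuclei at 0 h, 5.501 ± 2.49% at 24 h, 3.08 ± 0.0604% at 36 h, 2.01 ± 0.515% at 48 h and 2.596 ± 1.75% at 54 h (SD, n = 3, 3, 3, 3 and 4). The slope was -2.603 percentage points per 10 h (permutation test, p = 5.0e-05, adjusted p = 0.00085 over 17 classes). With coarser clusters, at resolution 0.5, it was -1.98 (adjusted p = 0.058). Oligodendrocyte precursors went from 5.54 ± 3.79% at 0 h to 1.596 ± 0.323% at 24 h and 1.195 ± 1.102% at 54 h (slope -0.785, permutation test, adjusted p = 0.0051). In both classes all 4 libraries of 54 h lay below all 3 of 0 h (exact permutation p = 0.0286, the smallest that 3 against 4 allows, adjusted p = 0.16). CA1 pyramidal cells, the output neurons of the hippocampus, were 8.12 ± 7.05% at 0 h and 17.7 ± 6.87% at 54 h (slope 2.25, permutation test, adjusted p = 0.056). That slope passed without 0 h replicate 3 (2.67, adjusted p = 0.042) and without 54 h replicate 1 (2.73, adjusted p = 0.0062). Microglia went from 6.08 ± 4.98% to 1.37 ± 0.481% (slope -0.761, adjusted p = 0.13) and dentate granule cells from 20.9 ± 17.98% to 37.4 ± 4.95% (slope 2.78, adjusted p = 0.13).

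Cajal-Retzius cells, early-born neurons of the outer layer, had a slope of 0.10 percentage points per 10 h (permutation test, adjusted p = 0.090), which was 0.134 without 0 h replicate 1 (adjusted p = 0.025) and 0.118 without 54 h replicate 2 (adjusted p = 0.043). Fibroblasts, cells of the meninges, had a slope of -0.695 (adjusted p = 0.13), but -0.0521 without 0 h replicate 1 (adjusted p = 0.60, range 0.0025 to 0.60 over all alternatives). The slopes of the other 10 classes had adjusted p of 0.21 or more. Thalamic neurons, from tissue beside the hippocampus, were 8.48% in 54 h replicate 1, 5.51% in replicate 4 and 0 in replicates 2 and 3, against 0.0152 ± 0.0186% at 0 h. Shares add up to 100%, so a fall in 1 class lifts the others. Clusters that no fixed marker set named held 2.43 to 40.8% of the kept nuclei of a library at 0 h, 4.98 to 18.1% at 24 h, 8.64 to 48.8% at 36 h, 7.55 to 24.8% at 48 h and 7.58 to 33.9% at 54 h, and these nuclei enter the sums over all nuclei.

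**Figure D2:**
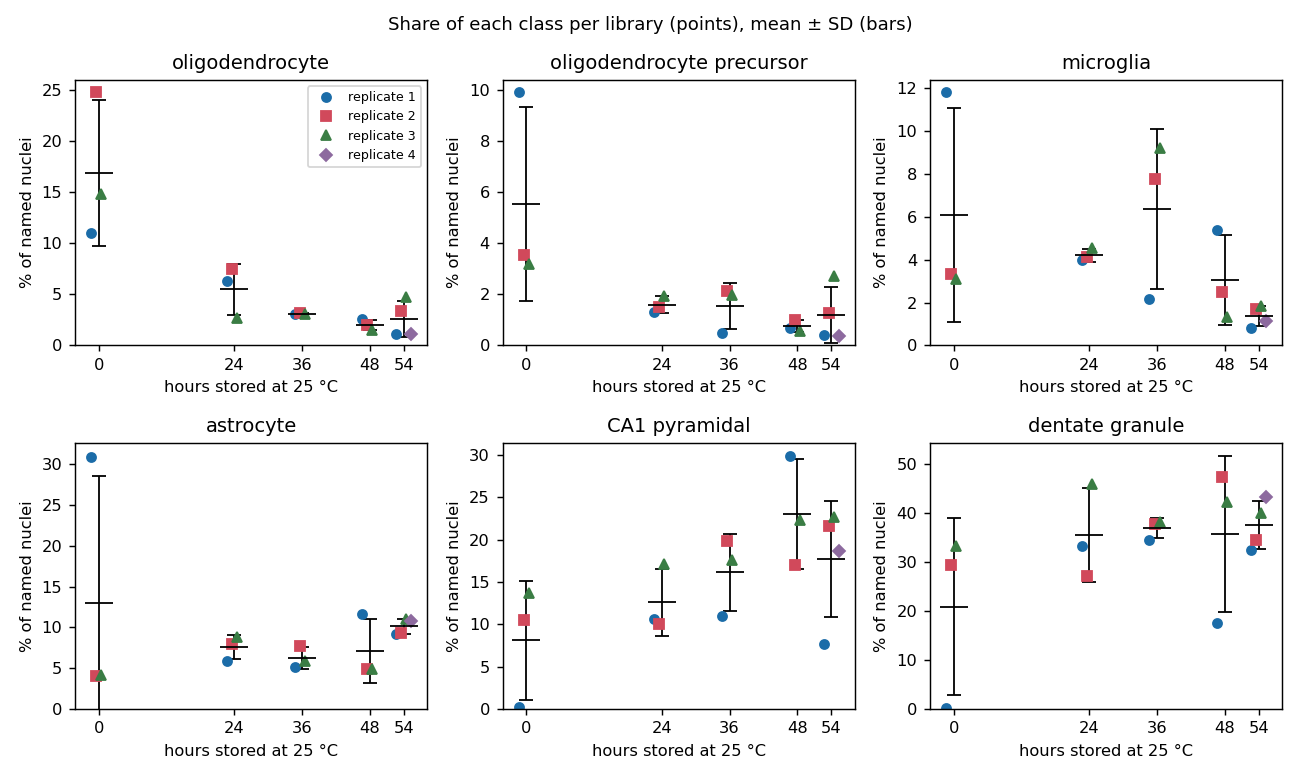
Percent of named nuclei in 6 classes (vertical axes) by hours at 25 °C (horizontal axis), each point a library and bars the mean ± SD. Oligodendrocytes took 10.96 to 24.8% in the 3 libraries of 0 h and 1.15 to 7.51% in the 13 stored ones.

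After 24 h at 25 °C, the sums over all nuclei held more transcripts of immediate early genes, and fewer of genes of the oligodendrocyte line, than at 0 h. Egr1 (ENSMUSG00000038418, chromosome 18, 34859823 to 34864984 in mm10), a transcription factor switched on within minutes of stimulation, had a log2 fold change of 2.71 ± 0.46 (SE, edgeR adjusted p = 0.0017), from 9.59 ± 2.92 to 62.5 ± 38.6 CPM (SD, n = 3 and 3). Also higher, in log2 fold change ± SE, were the AP-1 factors Fosb (5.41 ± 0.63), Fos (3.47 ± 0.58), Junb (2.17 ± 0.34) and Jund (1.80 ± 0.42), the calcium sensor Hpca (1.86 ± 0.42), the neuropeptide Npy (1.83 ± 0.44) and the dynein light chain Dynll1 (1.78 ± 0.44), with edgeR adjusted p 0.00030 to 0.010. Among the largest falls were those of Cdh19 (-3.94 ± 0.53), a cadherin of glia, Fign (-3.69 ± 0.96), a microtubule-severing enzyme, Aspa (-3.19 ± 0.42), which splits acetylaspartate in oligodendrocytes, Ptgds (-3.08 ± 0.67), prostaglandin D synthase, the myelin surface protein Mog (-2.94 ± 0.42), Prr5l (-2.94 ± 0.47) and the growth factor Fgf1 (-2.72 ± 0.38), with edgeR adjusted p 0.00049 to 0.013. Sums over all nuclei also hold changes of composition, such as the lower share of oligodendrocytes.

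By gene list at 24 h, 14 of the 20 immediate early genes rose and 0 fell (16 and 0 adjusted over the list alone, median 1.54, camera adjusted p = 4.8e-11, 0.29 with an estimated correlation). 12 of the 12 myelin genes fell and 0 rose (median -2.05, camera adjusted p = 4.8e-11, 0.29 with an estimated correlation), the medians being log2 fold changes. Where no count adjusted over the list alone is given, here and below, it was the same. The very long neuronal genes span the largest stretches of the genome. 13 of the 25 very long neuronal genes fell and 0 rose (15 and 0 adjusted over the list alone, median -0.53, camera adjusted p = 1.3e-07, 0.29 with an estimated correlation), with Erbb4 (-1.56 ± 0.23) and Pcdh9 (-1.27 ± 0.16). Fewer protein-folding genes passed: of the 16 heat shock and chaperone genes, 3 rose and 0 fell (2 and 0 adjusted over the list alone, median 0.49), with Dnajb1 (2.06 ± 0.34). Of the 15 unfolded protein response genes, 5 rose and 0 fell (median 0.41), with the stress regulator Atf4 (1.54 ± 0.35). Of the 16 glycolysis genes, 5 rose and 0 fell (11 and 1 adjusted over the list alone, median 0.80, camera adjusted p = 0.00068, 0.49 with an estimated correlation), led by the isomerase Gpi1 (1.18 ± 0.17). There were 5741 genes past the threshold, 2499 higher and 3242 lower, of 21258 tested, with 8659 at an unadjusted p under 0.05. The count was 3508 without 0 h replicate 2, 3254 without 24 h replicate 1 and 3757 without 24 h replicate 2, and 9353 without all replicate 1 libraries. Camera called 10 of the 22 lists, and 0 with an estimated correlation (lowest adjusted p = 0.29).

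At 36 h, with 3 libraries against 3, there were 8538 genes past the threshold, 4087 higher and 4451 lower, of 21258 tested. The largest rises, in log2 fold change ± SE, were Fosb (6.63 ± 0.66), Fos (4.66 ± 0.60), Egr1 (3.60 ± 0.48) and Junb (3.18 ± 0.35). Next were Lars2 (2.83 ± 0.60), Tmsb4x (2.82 ± 0.58), Jund (2.81 ± 0.43) and Ppp3r1 (2.76 ± 0.53). The largest falls were Cdh19 (-5.68 ± 0.58), Ptgds (-5.15 ± 0.74), Aspa (-4.90 ± 0.46), Fign (-4.81 ± 1.02), Gjc3 (-4.77 ± 0.44), Ranbp3l (-4.67 ± 0.97), Mog (-4.44 ± 0.46) and Prr5l (-4.42 ± 0.51), of which Gjc3 is a connexin of oligodendrocytes. Of the fixed lists, 18 of the 20 immediate early genes rose and 0 fell (19 and 0 adjusted over the list alone, median 2.17, camera adjusted p = 1.2e-13, 0.20 with an estimated correlation). 11 of the 16 heat shock and chaperone genes rose and 0 fell (median 0.96, camera adjusted p = 0.00016, 0.38 with an estimated correlation). 12 of the 12 myelin genes fell and 0 rose (median -3.11, camera adjusted p = 1.2e-13, 0.20 with an estimated correlation). By 48 h there were 9557 genes past the threshold, 4723 higher and 4834 lower, of 21258 tested. Fosb (6.70 ± 0.66), Egr1 (3.57 ± 0.48), the inhibitory neuropeptide Sst (3.30 ± 0.45), Junb (3.10 ± 0.35), Jund (2.99 ± 0.44), Tmsb4x (2.93 ± 0.58), Tmsb10 (2.77 ± 0.55) and Lars2 (2.74 ± 0.60) rose most. Aspa (-5.36 ± 0.47), Gjc3 (-5.24 ± 0.45), Ptgds (-5.20 ± 0.74), Cdh19 (-5.15 ± 0.57), Prr5l (-5.13 ± 0.52), Fa2h (-4.91 ± 0.46), Mog (-4.71 ± 0.46) and Fign (-4.53 ± 1.00) fell most. Here 18 of the 20 immediate early genes rose and 0 fell (19 and 0 adjusted over the list alone, median 1.88, camera adjusted p = 4.2e-11, 0.20 with an estimated correlation). 10 of the 16 heat shock and chaperone genes rose and 0 fell (11 and 0 adjusted over the list alone, median 0.81, camera adjusted p = 0.00050, 0.37 with an estimated correlation). 12 of the 12 myelin genes fell and 0 rose (median -3.55, camera adjusted p = 8.2e-14, 0.12 with an estimated correlation). Camera called 13 of 22 lists at 36 h and 12 at 48 h, and 0 at either time with an estimated correlation.

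At 54 h, the longest storage, the AP-1 factor Fosb (ENSMUSG00000003545, chromosome 7, 19302696 to 19310051 in mm10) stood at 45.9 ± 24.5 CPM (SD, n = 4) against 0.5003 ± 0.105 at 0 h (SD, n = 3), a log2 fold change of 6.51 ± 0.64 (SE, edgeR adjusted p = 1.3e-05). Other large rises were Fos (4.69 ± 0.59), Egr1 (3.72 ± 0.47), Lars2 (3.16 ± 0.60), Gm42418 (3.02 ± 0.70), Junb (2.98 ± 0.34), mt-Atp8 (2.92 ± 0.96) and Jund (2.86 ± 0.42) in log2 fold change ± SE, with edgeR adjusted p 2.8e-05 to 0.024. Gene model Gm42418 overlaps ribosomal RNA and mt-Atp8 encodes part of ATP synthase. Lars2 and Cmss1 topped 1 coarser cluster with Gm42418, and a shared source was not tested. Aspa (ENSMUSG00000020774, chromosome 11, 73304992 to 73329596 in mm10) was the furthest below 0 h, at 2.48 ± 0.744 against 80.1 ± 34.03 CPM (log2 fold change -5.01 ± 0.41, adjusted p = 6.2e-06). It was followed by Gjc3 (-4.86 ± 0.39), Cdh19 (-4.83 ± 0.49), Ptgds (-4.67 ± 0.64), Mog (-4.50 ± 0.41), Fa2h (-4.46 ± 0.40), Prr5l (-4.40 ± 0.45) and Ranbp3l (-4.29 ± 0.85), with edgeR adjusted p 5.8e-06 to 0.0012. With 1 library left out, mt-Atp8 was 2.36 without 0 h replicate 3 (adjusted p = 0.056), with adjusted p from 9.4e-07 to 0.11 over all alternatives. There were 9114 genes past the threshold, 4528 higher and 4586 lower, of 21258 tested.

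Genes of the stress responses rose at 54 h. 19 of the 20 immediate early genes rose and 0 fell (median 2.11, camera adjusted p = 2.8e-10, 0.29 with an estimated correlation). 10 of the 16 heat shock and chaperone genes rose and 0 fell (12 and 0 adjusted over the list alone, median 0.95, camera adjusted p = 0.00019, 0.40 with an estimated correlation), among them the chaperones Dnajb1 (2.89 ± 0.34), Hsph1 (1.39 ± 0.21) and Dnaja1 (0.96 ± 0.22). 9 of the 15 unfolded protein response genes rose and 0 fell (10 and 0 adjusted over the list alone, median 1.06, camera adjusted p = 0.00039, 0.40 with an estimated correlation), led by the regulators Atf4 (2.22 ± 0.34) and Chac1 (2.50 ± 0.41) and by Asns (1.37 ± 0.18), which makes asparagine. In energy metabolism, of the 16 glycolysis genes, 11 rose and 0 fell (11 and 1 adjusted over the list alone, median 1.33, camera adjusted p = 7.2e-05, 0.40 with an estimated correlation), with Eno2 (1.64 ± 0.26), Pfkl (1.40 ± 0.25) and Gpi1 (1.25 ± 0.16). 9 of the 33 nuclear-encoded oxidative phosphorylation genes rose and 0 fell (2 and 0 adjusted over the list alone, median 0.82, camera adjusted p = 0.00015, 0.63 with an estimated correlation), with Ndufc1 (1.68 ± 0.41) and Atp5k (1.58 ± 0.40). The sole mitochondrially encoded gene past the threshold was mt-Atp8 (not without 0 h replicate 3, 2.36, adjusted p = 0.056), as of the 13 mitochondrially encoded genes, 1 rose and 0 fell (0 and 0 adjusted over the list alone, median -0.38, camera adjusted p = 0.13). For that list the signs of the median and of the test differed. Likewise Rpl4 (1.58 ± 0.43) was the sole call where of the 46 cytosolic ribosomal protein genes, 1 rose and 0 fell (0 and 0 adjusted over the list alone, median 0.80, camera adjusted p = 0.00010, 0.63 with an estimated correlation). Of the 18 hypoxia response genes, 5 rose and 1 fell (median 0.06, camera adjusted p = 0.26), with the mitophagy gene Bnip3 (1.41 ± 0.24) and hexokinase Hk2 (-2.63 ± 0.46). Of the 20 p53 and apoptosis genes, 8 rose and 2 fell (median 0.34, camera adjusted p = 0.13), with Gadd45b (2.30 ± 0.45), Mdm2 (0.50 ± 0.08) and Eda2r (-2.21 ± 0.44).

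Neuronal genes rose in part at 54 h, and myelin genes fell. 12 of the 18 presynaptic vesicle genes rose and 0 fell (13 and 0 adjusted over the list alone, median 0.69, camera adjusted p = 0.00070, 0.40 with an estimated correlation), among them Cplx1 (1.72 ± 0.26). Of the 16 GABA synapse genes, 8 rose and 1 fell (median 0.45, camera adjusted p = 0.019, 0.40 with an estimated correlation), with the vesicular transporter Slc32a1 (1.79 ± 0.35) and the receptor Gabbr1 (1.03 ± 0.16). Of the 21 glutamate synapse genes, 4 rose and 1 fell (median 0.37, camera adjusted p = 0.13), with Dlg4 (1.24 ± 0.21) and Slc17a7 (1.16 ± 0.21). Of the 16 voltage-gated ion channel genes, 6 rose and 1 fell (median 0.34, camera adjusted p = 0.064). Messengers carried into neurites included Tmsb10 (2.78 ± 0.54) and Nrgn (2.06 ± 0.38). 13 of the 20 neurite-localised mRNAs rose and 0 fell (median 1.28, camera adjusted p = 8.9e-05, 0.40 with an estimated correlation). 12 of the 12 myelin genes fell and 0 rose (median -3.13, camera adjusted p = 1.1e-13, 0.19 with an estimated correlation). 12 of the 25 very long neuronal genes fell and 0 rose (median -0.49, camera adjusted p = 0.00092, 0.40 with an estimated correlation), such as Pcdh9 (-1.23 ± 0.15) and Erbb4 (-1.09 ± 0.21). Of the 15 activated microglia genes, 3 rose and 6 fell (3 and 7 adjusted over the list alone, median -1.22, camera adjusted p = 0.29), where Trem2 (-4.02 ± 0.59) and Tyrobp (-3.37 ± 0.77) are also markers of microglia.

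The other lists at 54 h follow. Of the 14 reactive astrocyte genes, 1 rose and 4 fell (median -0.20, camera adjusted p = 0.84). Of the 15 inflammatory cytokine and NF-kB genes, 4 rose and 2 fell (median 0.38, camera adjusted p = 0.26), with Cebpb (2.31 ± 0.26) and Nlrp3 (-3.04 ± 0.76). Of the 13 nuclear-retained long noncoding RNAs, 4 rose and 3 fell (median 0.25, camera adjusted p = 0.26), with Malat1 (-1.34 ± 0.23) and Peg13 (2.33 ± 0.40). 8 of the 16 circadian clock genes rose and 0 fell (median 0.34, camera adjusted p = 0.012, 0.19 with an estimated correlation), with Bhlhe40 (1.31 ± 0.26), Per1 (0.78 ± 0.14) and Tef (0.73 ± 0.12). Of the 20 RNA decay and splicing genes, 8 rose and 2 fell (8 and 3 adjusted over the list alone, median 0.15, camera adjusted p = 0.099), with Upf1 (1.06 ± 0.18) and Rbm3 (0.97 ± 0.17). Camera called 12 of the 22 lists, none of which passed with an estimated correlation. Fry, which asks whether members move on balance 1 way, called 13.

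Markers of glia and immune cells fell in the same sums at 54 h. 10 of 10 oligodendrocyte markers fell and 0 rose (median -2.89), such as St18 (-1.79 ± 0.20) and Mbp (-1.82 ± 0.30, -0.31 and not called in weighted sums). 8 of 10 oligodendrocyte precursor markers fell and 0 rose (median -2.15) and 7 of 12 astrocyte markers fell and 0 rose (10 and 0 adjusted over the list alone, median -2.01). 9 of 10 microglia markers fell and 0 rose (median -3.25), such as P2ry12 (-2.97 ± 0.30), and 3 of 5 other immune cell markers fell and 0 rose (4 and 0 adjusted over the list alone, median -3.30). Here 5 of 8 excitatory neuron markers rose and 0 fell (6 and 0 adjusted over the list alone, median 1.19) and 4 of 6 CA1 pyramidal markers rose and 0 fell (median 1.19). 2 of 8 CA3 pyramidal markers rose and 0 fell (median 0.32), 7 of 11 inhibitory neuron markers rose and 1 fell (median 1.63) and 3 of 6 Cajal-Retzius markers rose and 0 fell (4 and 0 adjusted over the list alone, median 1.03). By contrast, 0 of 8 dentate granule markers rose and 0 fell (median 0.31), 3 of 8 subicular and cortical excitatory markers fell and 0 rose (median -0.63) and 1 of 5 immature neuron markers fell and 0 rose (median -0.51). 0 of 8 endothelial markers rose and 0 fell (median -0.85). 0 of 7 mural markers rose and 0 fell (median -0.45) and 2 of 7 fibroblast markers fell and 0 rose (median -2.83). Elsewhere, 1 of 6 choroid plexus markers rose and 1 fell (median 1.24). 0 of 7 ependymal markers rose and 0 fell (median 0.27), 1 of 5 thalamic neuron markers rose and 0 fell (0 and 0 adjusted over the list alone, median 1.36), 2 of 6 striatal neuron markers rose and 0 fell (3 and 0 adjusted over the list alone, median 0.46) and 1 of 5 erythrocyte markers fell and 0 rose (median -0.64).

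Between the first and the last stored time point, 54 h against 24 h, edgeR called 1 gene, against 3121 at an unadjusted p under 0.05 and 787 called by DESeq2. The gene, chosen after its values were seen, was Gm50035 (ENSMUSG00000117404, chromosome 18, 15201112 to 15207791 in mm10), an unnamed noncoding RNA inside another one on the opposite strand. Its log2 fold change was -4.76 ± 0.57 (SE, edgeR adjusted p = 0.018, and 0.058 to 0.17 without any one of 24 h replicates 2 and 3 and 54 h replicates 1, 2, 3 and 4), with 5.15 ± 0.9002 CPM at 0 h, 0.641 ± 0.0978 at 24 h and 0.0231 ± 0.007400 at 54 h (SD, n = 3, 3 and 4). Which of the overlapping RNAs was counted is uncertain, since the strand counted is not given in the sources used here. Camera called 12 of 22 lists, and 0 with an estimated correlation, while fry called 0. No list member passed over all genes. For example, 0 of the 12 myelin genes fell and 0 rose (7 and 0 adjusted over the list alone, median -1.08, camera adjusted p = 4.7e-09, 0.24 with an estimated correlation), with a value for Aspa of -1.82 ± 0.37 (-1.84 without 0 h replicate 1 (adjusted p = 0.039), with adjusted p from 0.0010 to 0.34 over all alternatives). Of the 20 immediate early genes, 0 rose and 0 fell (median 0.77, camera adjusted p = 0.00026, 0.56 with an estimated correlation), with values of Fos (1.22 ± 0.49) and Jund (1.06 ± 0.39). The count of genes depended on the libraries used, being 405 without 0 h replicate 1, 245 without 24 h replicate 1, 0 without any one of 24 h replicates 2 and 3 and 54 h replicates 1, 2 and 4 and 75 without 36 h replicate 1. It was 4146 without all replicate 1 libraries, 377 with class sums weighted to 1 composition, and 80 with the libraries of these times alone.

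In dentate granule neurons, the input cells of the hippocampus, transcripts of the mitochondrial genome and of ribosomal proteins were higher after storage than in 0 h replicates 2 and 3, and those of myelin lower. At 24 h mt-Atp6 (3.74 ± 0.61), mt-Nd1 (3.67 ± 0.55), Rps24 (3.46 ± 0.28) and mt-Nd2 (3.44 ± 0.53) rose most and Ptgds (-2.65 ± 0.41), Timp3 (-2.63 ± 0.25) and Rapgef4os1 (-2.61 ± 0.30) fell most, in log2 fold change ± SE (n = 3 and 2, edgeR adjusted p 5.1e-06 to 0.00027). At 54 h it was mt-Atp8 (6.35 ± 0.52), mt-Nd5 (5.23 ± 0.46) and mt-Nd4l (5.05 ± 0.65) against Ptgds (-4.84 ± 0.41), Macrod2os1 (-3.75 ± 0.40) and Sorbs2os (-3.44 ± 0.35) (n = 4 and 2, edgeR adjusted p 5.4e-07 to 1.8e-05). Names with os at their end are antisense models, uncertain here, and mt-Atp8 and mt-Nd4l overlap mt-Atp6 and mt-Nd4. At 54 h 13 of 13 mitochondrially encoded genes rose and 0 fell (median 3.74, camera adjusted p = 1.9e-10, 0.26 with an estimated correlation). 46 of 46 cytosolic ribosomal protein genes rose and 0 fell (median 2.62, camera adjusted p = 1.3e-36, 0.20 with an estimated correlation). 11 of 12 myelin genes fell and 0 rose (median -4.18, camera adjusted p = 4.8e-10, 0.20 with an estimated correlation), with Cldn11 (-5.13 ± 0.40), Mog (-4.82 ± 0.37) and Cnp (-2.94 ± 0.23). Also 14 of 20 immediate early genes rose and 0 fell (16 and 0 adjusted over the list alone, median 2.59), with Jund (3.51 ± 0.71), Btg2 (3.05 ± 0.62) and Jun (2.51 ± 0.50). The 18 nuclei of 0 h replicate 1, too few to be a control, had a median of 0.424% mitochondrial UMIs, within the 0.0693 to 0.477% of stored libraries. Of these cells, 98.8% lay in cluster 4 at 0 h and 91.96% in cluster 0 at 54 h. EdgeR called 6742 genes at 24 h (3081 higher, 3661 lower), 4076 without 0 h replicate 2 and 4466 without 0 h replicate 3. The count at 54 h was 8098 (3923 and 4175) of 17266 tested.

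In CA1 pyramidal neurons mt-Nd1 (4.30 ± 0.72), mt-Atp6 (4.17 ± 0.64), mt-Nd2 (3.99 ± 0.64) and mt-Cytb (3.98 ± 0.65) were highest at 24 h. Ptgds (-2.71 ± 0.42), Lrtm1 (-2.66 ± 0.49) and Ggact (-2.23 ± 0.33) were lowest (n = 3 and 2). At 54 h the actin-binding Tmsb10 (4.49 ± 0.47) stood beside mt-Nd5 (5.37 ± 0.61), mt-Nd2 (4.42 ± 0.64) and mt-Nd1 (4.37 ± 0.71), and Macrod2os1 (-4.77 ± 0.53), Lrtm1 (-4.64 ± 0.48) and Nrg3os (-4.25 ± 0.47) were lowest (n = 4 and 2, edgeR adjusted p 9.1e-06 to 0.00025). Here 13 of 13 mitochondrially encoded genes rose and 0 fell (median 4.08). 45 of 46 cytosolic ribosomal protein genes rose and 0 fell (median 2.37). 11 of 12 myelin genes fell and 0 rose (median -4.27). In the 15 nuclei of 0 h replicate 1, not among the controls, the median of mitochondrial UMIs was 0.324%, above the 0.03199 to 0.2605% of stored libraries. Median UMIs per CA1 nucleus were 5175 to 6279 at 0 h and 9838 to 22604 in stored libraries, and the nuclei lay in cluster 14 at 0 h and cluster 2 later. Past the threshold were 4164 genes at 24 h (1918 higher, 2246 lower), 1139 without 0 h replicate 2 and 1277 without 0 h replicate 3. By 54 h it was 7216 (3495 and 3721) of 16750 tested, 4782 without 0 h replicate 2. CA3 pyramidal neurons, which feed CA1, had mt-Nd3 (4.52 ± 0.60), Tmsb4x (3.02 ± 0.45), Rpl32 (2.93 ± 0.46) and Rps24 (2.86 ± 0.49) highest and Lrtm1 (-3.49 ± 0.31), Ptgds (-3.12 ± 0.43), Macrod2os1 (-3.01 ± 0.33) and Plxna4os3 (-2.94 ± 0.35) lowest at 24 h (n = 3 and 3). At 54 h it was mt-Nd4l (4.54 ± 0.77), mt-Nd5 (4.53 ± 0.67) and Rpl32 (3.76 ± 0.46) and the mitochondrial import gene Tomm6 (3.57 ± 0.44) against Ptgds (-5.63 ± 0.49), Lrtm1 (-4.91 ± 0.32), Macrod2os1 (-4.48 ± 0.34) and Sorbs2os (-4.34 ± 0.38) (n = 4 and 3). 9 of 13 mitochondrially encoded genes rose and 0 fell (median 2.80). 10 of 11 myelin genes fell and 0 rose (median -4.66). The cells lay in cluster 35 at 0 h and in cluster 6 later. The calls came to 3930 genes at 24 h (1856 higher, 2074 lower), 2221 without 0 h replicate 2 and 2286 without 0 h replicate 3. At 54 h there were 5035 (2588 and 2447) of 13966 tested.

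In excitatory neurons of the subiculum and cortex, mt-Nd5 (3.37 ± 0.83), the tubulin Tuba1b (3.15 ± 0.50), Egr1 (3.00 ± 0.54) and Dynll2 (2.79 ± 0.51) were highest at 24 h. Fgf1 (-3.84 ± 0.58), Lrtm1 (-3.38 ± 0.60), Pcsk2os2 (-3.34 ± 0.44) and Macrod2os1 (-3.04 ± 0.51) were lowest (n = 3 and 3). Here mt-Nd5 was 2.32 without 0 h replicate 2 (adjusted p = 0.090) and 2.37 without 0 h replicate 3 (adjusted p = 0.095), with adjusted p from 2.2e-05 to 0.095 over all alternatives. At 54 h Fosb stood at 99.6 ± 53.1 against 0.351 ± 0.309 CPM (7.55 ± 0.87, edgeR adjusted p = 3.6e-05), before mt-Atp8 (6.50 ± 0.58), mt-Nd4l (4.85 ± 0.66) and Tmsb10 (4.68 ± 0.45), and Ptgds (-6.06 ± 0.43), Lrtm1 (-4.61 ± 0.60), Pcsk2os2 (-4.57 ± 0.46) and Sorbs2os (-4.38 ± 0.52) were lowest (n = 4 and 3). 19 of 19 immediate early genes rose and 0 fell (median 2.89, camera adjusted p = 2.2e-18, also past at 0.049 with an estimated correlation). 13 of 15 heat shock and chaperone genes rose and 0 fell (median 1.88), with Dnajb1 (4.52 ± 0.44) and Hspa1a (4.47 ± 0.65). 10 of 12 myelin genes fell and 0 rose (median -3.59). Clusters 24, 39 and 44 held the class at 0 h and clusters 15, 18, 22 and 29 later. In this class edgeR called 3623 genes at 24 h (1758 higher, 1865 lower), 1471 without 0 h replicate 2 and 1737 without 0 h replicate 3. The count at 54 h was 5606 (2989 and 2617) of 15619 tested.

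**Figure D3:**
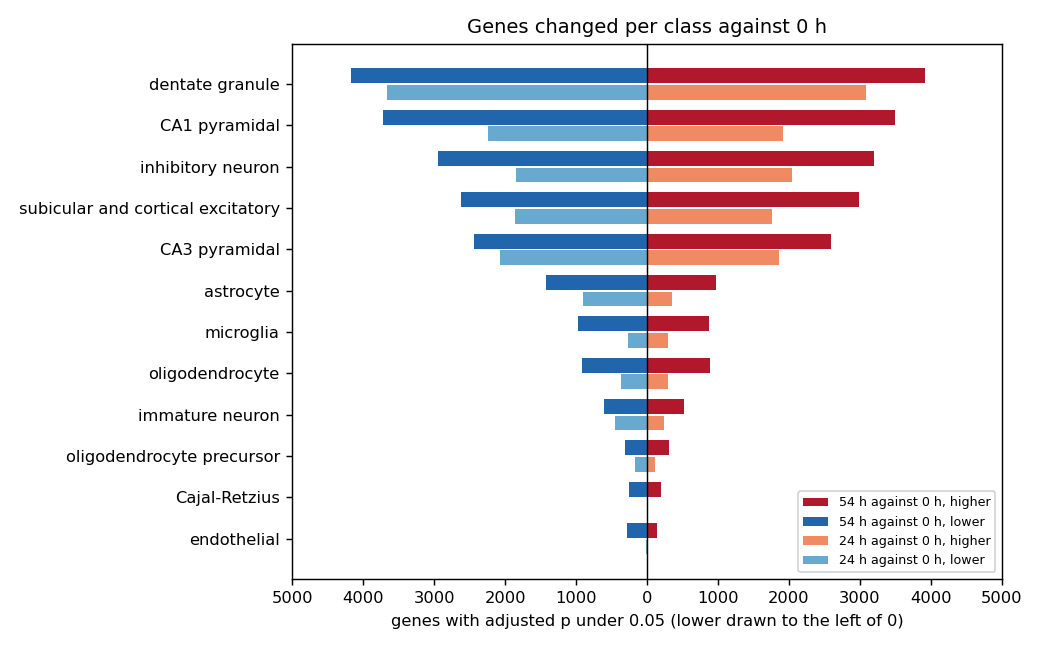
Number of genes past the threshold per class (horizontal axis, lower genes drawn to the left of 0) at 24 h and 54 h against 0 h (bars). The bars of dentate granule cells reach 3923 higher and 4175 lower genes at 54 h.

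The sums over inhibitory neurons of stored tissue held more transcripts of the neuropeptides Npy and Sst, which are also among the fixed markers of the class. At 24 h Npy (4.36 ± 0.47) and Sst (3.92 ± 0.58), the dynein light chain Dynll2 (3.10 ± 0.43) and Nap1l5 (2.98 ± 0.40) were highest. Apoe (-4.02 ± 0.87), Ptgds (-3.67 ± 0.67), Lrtm1 (-3.16 ± 0.43) and Sox5os4 (-3.14 ± 0.36) were lowest (n = 3 and 3). At 54 h Sst stood at 1721 ± 608 against 78.9 ± 87.6 CPM (4.46 ± 0.58, edgeR adjusted p = 2.3e-05), with Dynll2 (4.02 ± 0.43), Npy (3.94 ± 0.45) and Nap1l5 (3.88 ± 0.41) next and Ptgds (-6.06 ± 0.71), Apoe (-5.21 ± 0.84) and Grip1os2 (-4.64 ± 0.45) lowest (n = 4 and 3). 12 of 15 heat shock and chaperone genes rose and 0 fell (13 and 0 adjusted over the list alone, median 1.53), with Dnajb1 (3.00 ± 0.48) and Dnaja1 (1.53 ± 0.24). 11 of 13 unfolded protein response genes rose and 0 fell (median 1.20), with Atf4 (3.27 ± 0.49) and Ddit3 (1.94 ± 0.28). 13 of 16 glycolysis genes rose and 0 fell (median 1.21), with Tpi1 (2.15 ± 0.29) and Pkm (2.00 ± 0.27). 29 of 33 nuclear-encoded oxidative phosphorylation genes rose and 0 fell (median 1.66, camera adjusted p = 2.6e-09, 0.47 with an estimated correlation), while 24 of 25 very long neuronal genes fell and 0 rose (25 and 0 adjusted over the list alone, median -0.87). 11 of 12 myelin genes fell and 0 rose (median -3.51). Of the 13 mitochondrially encoded genes, 1 rose and 0 fell (median 0.00, camera adjusted p = 0.15). Without 0 h replicate 1, which is not among the controls of dentate granule and CA1 cells, 13 rose (median 3.74). Cluster 36 held 59.2% of the class at 0 h and cluster 16 44.98% at 54 h, the others lying in clusters 21 and 32, and this mix was not held fixed. EdgeR called 3891 genes at 24 h (2047 higher, 1844 lower), 2376 without 0 h replicate 2 and 2540 without 0 h replicate 3. By 54 h it was 6156 (3205 and 2951) of 13976 tested.

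Immature neurons, the newborn cells of the dentate gyrus, lay in 1 cluster at each time. At 24 h Tmsb10 (2.65 ± 0.42), Rpl26 (2.36 ± 0.47), Rps24 (2.33 ± 0.53) and Rpl7 (2.17 ± 0.36) were highest. Homeobox gene Meis2 (-3.81 ± 0.74), Filip1l (-3.29 ± 0.36), Ptgds (-2.90 ± 0.39) and Apoe (-2.76 ± 0.54) were lowest (n = 3 and 3). At 54 h it was Tmsb10 (5.23 ± 0.43), Lars2 (4.56 ± 0.51), Gm42418 (4.44 ± 0.54) and Rps24 (4.19 ± 0.55) against Ptgds (-4.78 ± 0.51), Plxna4os3 (-4.03 ± 0.56), Ctnna3 (-3.81 ± 0.34) and Nrg3os (-3.71 ± 0.32) (n = 4 and 3). 45 of 46 cytosolic ribosomal protein genes rose and 0 fell (46 and 0 adjusted over the list alone, median 2.57, camera adjusted p = 1.1e-65, also past at 0.049 with an estimated correlation). 20 of 25 very long neuronal genes fell and 0 rose (median -0.94, camera adjusted p = 1.5e-11, also past at 0.011 with an estimated correlation), such as Cntnap2 (-1.67 ± 0.23) and Lsamp (-1.21 ± 0.18). The chaperone Dnajb1, without a UMI at 0 h, was at least 16.95-fold higher. Past the threshold were 697 genes at 24 h (241 higher, 456 lower), 453 without 0 h replicate 2. At 54 h there were 1130 (517 and 613) of 6947 tested. In Cajal-Retzius cells, also 1 cluster, Hnrnpa0 was 38.6 times (95% counting interval 6.75 to 1543) and Islr 15.7 times (95% counting interval 4.18 to 132) at 54 h their UMI share at 0 h, where 1 and 2 UMIs were counted. Gm42418 (3.27 ± 0.60) and Lars2 (3.22 ± 0.62) were also high, and Ptgds (-5.03 ± 0.71), Ctnna3 (-4.28 ± 0.56) and Apoe (-3.97 ± 0.69) lowest (n = 4 and 3). The last was not called with 1 library left out, as Apoe was -2.09 without 0 h replicate 1 (adjusted p = 0.063), with adjusted p from 2.7e-28 to 0.063 over all alternatives. 26 of 46 cytosolic ribosomal protein genes rose and 0 fell (39 and 0 adjusted over the list alone, median 1.63), with Rps24 (2.93 ± 0.50) and Rpl26 (2.57 ± 0.50). 6 of 21 glutamate synapse genes fell and 0 rose (9 and 0 adjusted over the list alone, median -1.23), with Slc17a7 (-1.76 ± 0.37). For the class edgeR called 0 genes at 24 h (23 without 0 h replicate 1, 1 without 24 h replicate 2 and 2 without 48 h replicate 1), with 528 at an unadjusted p under 0.05 and 7 by DESeq2, and 451 of 5279 at 54 h (197 higher, 254 lower), 274 without 0 h replicate 2, 283 without 0 h replicate 3, 697 without 48 h replicate 1 and 264 without 54 h replicate 1.

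Astrocytes, the glia that take up transmitter and potassium, lost transcripts of very long genes. At 54 h 25 of 25 very long neuronal genes fell and 0 rose in astrocytes (median -1.51, camera adjusted p = 4.8e-23, 0.073 with an estimated correlation), such as Pcdh9 (-1.94 ± 0.19) and Lrp1b (-1.70 ± 0.20). At 24 h the highest genes were Lars2 (2.97 ± 0.49), Gm26917 (2.87 ± 0.28) and Gm42418 (2.62 ± 0.52) and the kinase Camk1d (2.20 ± 0.31), and the lowest Pard3bos1 (-4.73 ± 0.44), Wdr17 (-4.21 ± 0.30), Iqch (-4.18 ± 0.61) and P2ry14 (-3.86 ± 0.40) (n = 3 and 3). At 54 h Wdr17 stood at 155 ± 35.6 against 4639 ± 805 CPM (-4.90 ± 0.28, edgeR adjusted p = 1.9e-09), beside Pard3bos1 (-5.01 ± 0.46), P2ry14 (-4.89 ± 0.45) and Insyn2a (-4.40 ± 0.41), and the highest were Il31ra (6.39 ± 1.25), Lars2 (5.15 ± 0.53), Gm42418 (4.80 ± 0.56) and Cmss1 (4.71 ± 1.23) (n = 4 and 3). Of 21 glutamate synapse genes, 2 rose and 11 fell (2 and 13 adjusted over the list alone, median -0.59). 11 of 16 voltage-gated ion channel genes fell and 0 rose (12 and 0 adjusted over the list alone, median -0.94). 7 of 14 immediate early genes rose and 0 fell (8 and 0 adjusted over the list alone, median 1.39), with Egr1 (2.82 ± 0.37) and Jund (1.81 ± 0.34). 6 of 16 glycolysis genes rose and 0 fell (13 and 0 adjusted over the list alone, median 0.77), with Aldoc (1.85 ± 0.29) and Gpi1 (1.51 ± 0.20). Clusters 10 and 38 held the class at 0 h, and cluster 5 held 92.3% of it at 54 h. The calls came to 1258 genes at 24 h (352 higher, 906 lower), 1895 without 48 h replicate 1. The count at 54 h was 2394 (966 and 1428) of 10548 tested.

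Oligodendrocytes of stored tissue held more myelin and immediate early transcripts per UMI than those of 0 h. At 24 h Fosb (7.83 ± 1.03), Fos (7.06 ± 0.84) and mt-Atp8 (3.45 ± 0.75) were highest. Galnt5 (-5.36 ± 0.67), Slc13a1 (-5.25 ± 0.65) and Ggact (-3.81 ± 0.46) were lowest (n = 3 and 3). At 54 h Fosb stood at 554 ± 361 against 0.538 ± 0.0627 CPM (9.63 ± 1.03, edgeR adjusted p = 5.4e-06) and Fos at 808 ± 395 against 1.88 ± 1.17 CPM (8.57 ± 0.87), with Ier2 (6.64 ± 0.69) and the cytokine receptor Il31ra (6.60 ± 0.85) next, and Slc13a1 (-4.79 ± 0.77), Insyn2a (-4.25 ± 0.63) and Fbxw15 (-4.13 ± 0.64) were lowest (n = 4 and 3). 11 of 12 immediate early genes rose and 0 fell (12 and 0 adjusted over the list alone, median 4.13, camera adjusted p = 1.6e-19, also past at 0.030 with an estimated correlation). 6 of 8 unfolded protein response genes rose and 0 fell (7 and 0 adjusted over the list alone, median 2.11, camera adjusted p = 7.1e-08, also past at 0.043 with an estimated correlation), with Ppp1r15a (4.82 ± 0.49) and Hspa5 (2.42 ± 0.40). Of 12 myelin genes, 8 rose and 1 fell (9 and 1 adjusted over the list alone, median 1.11, camera adjusted p = 0.00025, 0.14 with an estimated correlation), with Cnp (2.81 ± 0.33), Mal (2.10 ± 0.28) and Cldn11 (1.31 ± 0.24). 23 of 24 very long neuronal genes fell and 0 rose (median -1.43), such as Macrod2 (-1.78 ± 0.25). Clusters 7 and 27 held the class at 0 h and cluster 9 later. In this class edgeR called 665 genes at 24 h (299 higher, 366 lower), 1414 without 0 h replicate 1, 418 without 0 h replicate 2 and 394 without 0 h replicate 3. By 54 h it was 1801 (890 and 911) of 6587 tested, 1184 without 54 h replicate 2.

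Oligodendrocyte precursors, the dividing cells of this line, had Egr1 (3.91 ± 0.37), Jun (3.35 ± 0.32) and Lars2 (3.01 ± 0.63) high at 24 h and Tes (-3.98 ± 0.53), Sycp2 (-3.86 ± 0.40), Ctnna3 (-3.19 ± 0.40) and Bcas1os2 (-3.15 ± 0.55) low (n = 3 and 3). At 54 h Fos (7.27 ± 0.61), Lars2 (6.57 ± 0.74) and Gm42418 (6.20 ± 0.81) were highest, Ctnna3 (-4.49 ± 0.52) low, and the meiotic gene Sycp2, without a UMI at 54 h, at least 12.9-fold lower (n = 3 and 3). 6 of 7 immediate early genes rose and 0 fell (7 and 0 adjusted over the list alone, median 5.26, camera adjusted p = 1.6e-30, also past at 0.0033 with an estimated correlation), with Egr1 (5.45 ± 0.39) and Jun (5.26 ± 0.34). 18 of 25 very long neuronal genes fell and 0 rose (21 and 0 adjusted over the list alone, median -1.19). Cluster 23 held 85.1% of the class at 0 h and cluster 41 79.02% at 54 h. EdgeR called 282 genes at 24 h (108 higher, 174 lower), 655 without 0 h replicate 1, 130 without 0 h replicate 2, 155 without 0 h replicate 3, 181 without 24 h replicate 1, 432 without 36 h replicate 1, 440 without 48 h replicate 1 and 443 without 48 h replicate 2. At 54 h there were 619 (303 and 316) of 4165 tested, 316 without 54 h replicate 3.

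Microglia of stored tissue held more transcripts of chaperones, immediate early genes and NF-kB targets. At 24 h Egr1 (4.92 ± 0.65), Tex14 (4.83 ± 0.85), Ier5 (4.11 ± 0.72) and Jun (4.04 ± 0.51) were highest. Cdh19 (-3.07 ± 0.53) was low (n = 3 and 3). At 54 h the chaperone Hspa1a was 547 times (95% counting interval 146 to 4603) and Fosb 585 times (95% counting interval 157 to 4912) their UMI shares at 0 h, where each had 2 UMIs, and Iqcn, without a UMI at 0 h, at least 349.8-fold higher. Cdh19, without a UMI at 54 h, was at least 24.2-fold lower (n = 4 and 3). 13 of 17 immediate early genes rose and 0 fell (14 and 0 adjusted over the list alone, median 4.33, camera adjusted p = 4.5e-24, also past at 0.036 with an estimated correlation), with Egr1 (6.25 ± 0.67) and Fos (6.24 ± 0.65). 7 of 15 heat shock and chaperone genes rose and 0 fell (median 1.21, camera adjusted p = 3.1e-07, also past at 0.036 with an estimated correlation), with Hspa1b (7.39 ± 0.73) and Hsp90aa1 (2.92 ± 0.41). 8 of 13 unfolded protein response genes rose and 0 fell (9 and 0 adjusted over the list alone, median 2.03), with Ppp1r15a (6.05 ± 0.78) and Hspa5 (4.18 ± 0.59). 7 of 12 inflammatory cytokine and NF-kB genes rose and 0 fell (9 and 0 adjusted over the list alone, median 2.44), with Tnf (5.45 ± 0.89), Nfkbia (4.20 ± 0.59) and Cebpb (2.83 ± 0.60). Of 10 activated microglia genes, 3 rose and 1 fell (median 0.18), with Itgax (5.58 ± 0.88), Ctsd (2.14 ± 0.32) and B2m (1.87 ± 0.40). 9 of 12 myelin genes fell and 0 rose (10 and 0 adjusted over the list alone, median -2.54). Clusters 17 and 48 held the class at 0 h, and cluster 25 held 71.9% of it at 54 h. Past the threshold were 567 genes at 24 h (296 higher, 271 lower), 289 without 0 h replicate 2, 287 without 24 h replicate 1, 259 without 24 h replicate 3 and 1103 without 48 h replicate 1. The count at 54 h was 1854 (876 and 978) of 9980 tested.

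Endothelial cells, which line the vessels, rest on 2 libraries at 0 h, of 720 and 20 nuclei. At 24 h Hspa1a (6.63 ± 1.03), Hspa1b (6.09 ± 0.99) and Egr1 (5.40 ± 1.00) were highest and Wdr17 (-3.03 ± 0.38) low (n = 3 and 2). Without 0 h replicate 1 the adjusted p, with the log2 fold change where the other control held a UMI, was 0.20 for Hspa1a, 0.25 for Hspa1b, 0.28 for Egr1 (4.65) and 0.20 for Wdr17 (-2.41) (3.0e-13 to 0.28 over all alternatives). At 54 h Hspa1a (6.27 ± 1.02) was high, Fosb was 373 times (95% counting interval 127 to 1809) its UMI share at 0 h, where it had 3 UMIs, and Rgs20 (-5.13 ± 0.85), Ptgds (-4.79 ± 0.74) and Nrg3os (-4.72 ± 0.56) were lowest (n = 3 and 2), with adjusted p without 0 h replicate 1 of 0.051 for Hspa1a, 0.11 for Fosb, 0.10 for Rgs20 (-4.39) and 0.18 for Ptgds (-2.46) (1.7e-16 to 0.18 over all alternatives). 8 of 13 immediate early genes rose and 0 fell (11 and 0 adjusted over the list alone, median 2.79). 5 of 8 unfolded protein response genes rose and 0 fell (median 2.42). 20 of 24 very long neuronal genes fell and 0 rose (21 and 0 adjusted over the list alone, median -2.27). Cluster 20 held 94.2% of the class at 0 h and cluster 11 88.1% at 54 h. The calls came to 31 genes at 24 h (18 higher, 13 lower), 2 without 0 h replicate 1, 12 without 24 h replicate 3, 20 without 54 h replicate 1 and 19 without 54 h replicate 4. By 54 h it was 418 (139 and 279) of 5602 tested, 261 without 0 h replicate 3, 178 without 54 h replicate 1 and 263 without 54 h replicate 2.

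**Figure D4:**
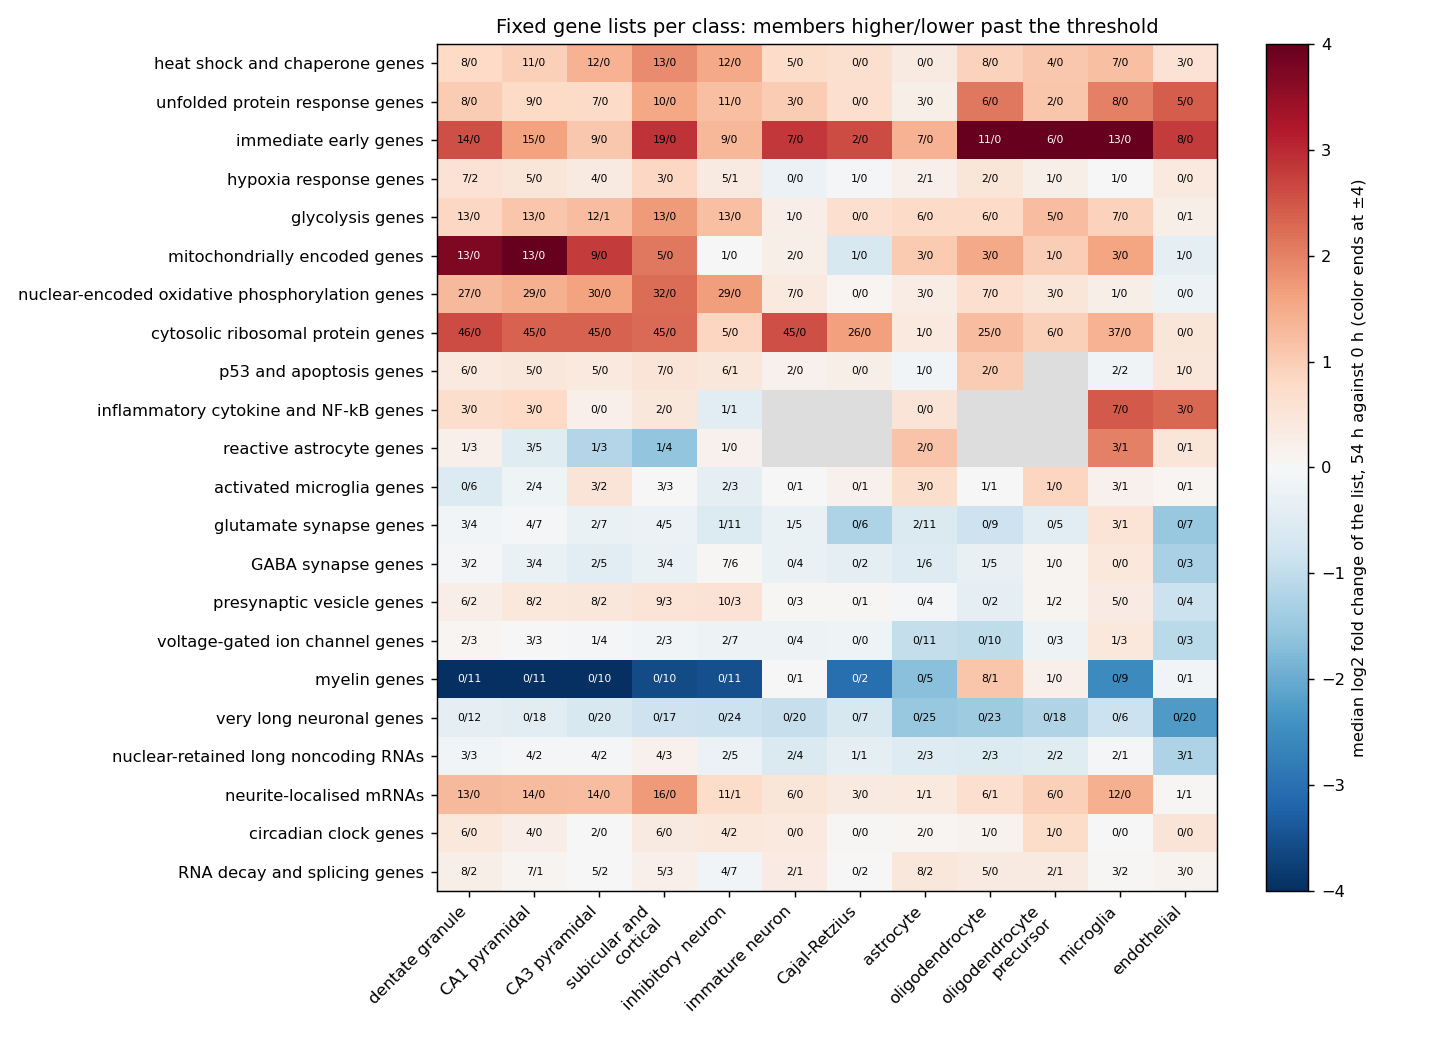
Median log2 fold change of each fixed gene list (vertical axis) in each tested class (horizontal axis), 54 h against 0 h, as color that ends at ±4, with the members higher and lower past the threshold printed in each field. The median of the myelin genes is -4.18 in dentate granule cells and 1.11 in oligodendrocytes.

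**Figure D5:**
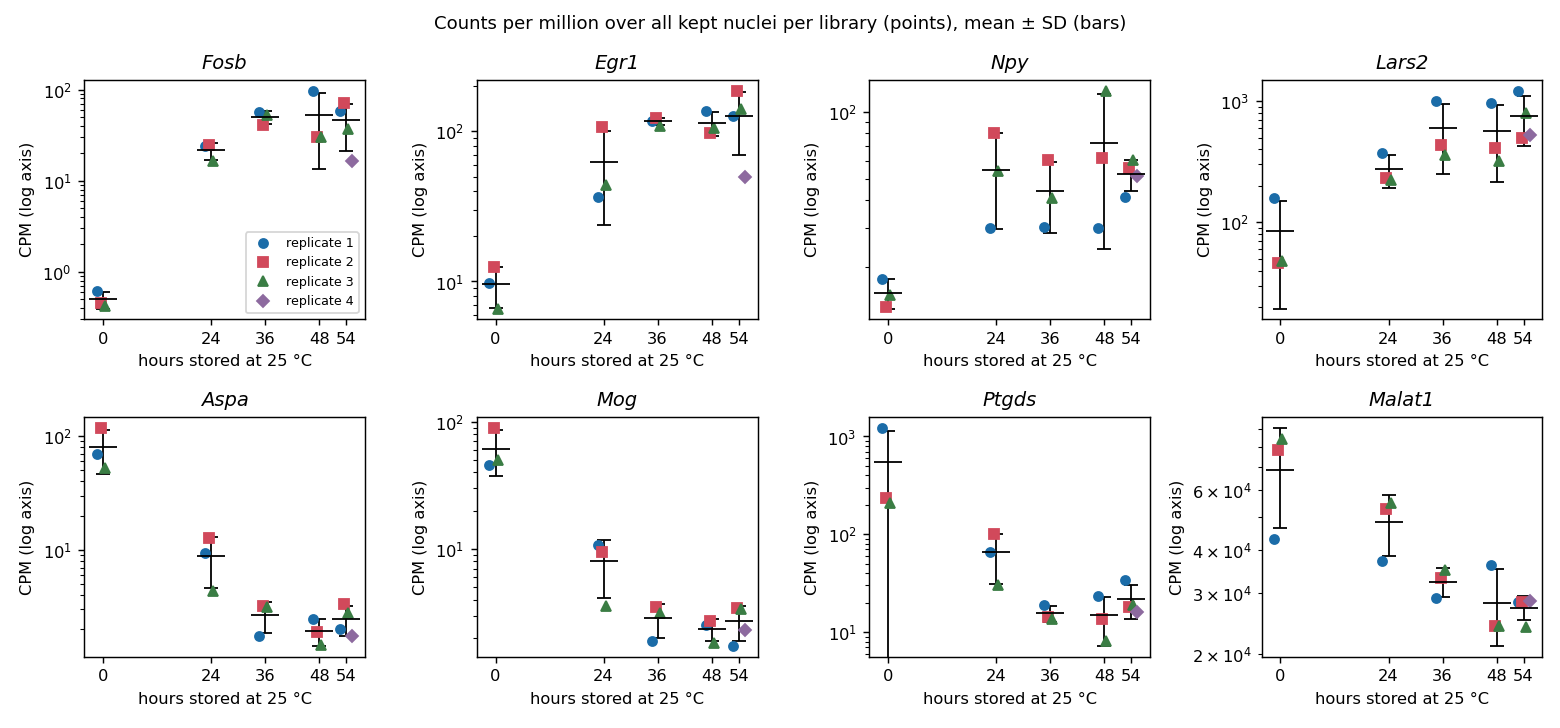
CPM (counts scaled to the library total) of 8 genes over all kept nuclei (vertical log axes) by hours at 25 °C (horizontal axis), each point a library and bars the mean ± SD. Fosb lies at 0.426 to 0.621 CPM at 0 h and 16.3 to 97.5 CPM in stored libraries.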

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

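The tests of free RNA for the myelin and the immediate early genes, the test of decay and the 4 pairs of classes were chosen only after the result was seen. At 54 h, replicate 1 lay far from the other 3 in shares of 4 classes of vessels and ventricles. Its named nuclei were 14.6% endothelial (0.706 to 0.889% in the other 3) and 4.001% choroid plexus cells (0). Mural cells were 2.99% (0.3296 to 0.6202%) and ependymal cells 1.29% (0.0942 to 0.247%). Of 22 groups of 4 libraries tested for 1 that stands apart, 4 had one, all in this library, where chance gives about 1 in 20. Shares of 1 library are linked, so these are not 4 separate signals. Replicate 1 also had the highest endothelial share at the times of 3 libraries (2.70 to 9.87%, 8.64% at 0 h), not tested.

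Whether the response at 54 h against 0 h differs was tested in 4 pairs of classes with a class by time interaction in edgeR (adjusted p under 0.05), higher meaning a greater log2 fold change. For dentate granule cells and CA1 cells, 319 genes of 17730 differed (151 higher in dentate granule cells and 168 in CA1 cells, 1598 at an unadjusted p under 0.05). For dentate granule cells and inhibitory neurons, 1133 genes of 16859 differed (385 higher in dentate granule cells and 748 in inhibitory neurons, 3739 unadjusted). For dentate granule cells and microglia, 770 genes of 18257 differed (294 higher in dentate granule cells and 476 in microglia, 3382 unadjusted). For astrocytes and oligodendrocytes, 104 genes of 10377 differed (26 higher in astrocytes and 78 in oligodendrocytes, 1326 unadjusted). Oligodendrocytes had a log2 fold change above that of astrocytes for 4 of 16 (3, -2.38) immediate early genes and 6 of 12 (7, -2.78) myelin genes, and inhibitory neurons one above that of dentate granule cells for 11 of 33 (30, -1.27) oxidative phosphorylation genes, 4 of 16 (10, -1.03) glycolysis genes and 6 of 16 (7, -0.05) GABA synapse genes, with the count with the library as a block and the median difference in parentheses. For astrocytes and oligodendrocytes 2 of 35 splits gave as many genes (104 in the real groups, 139 at most otherwise), so chance is not excluded. No splits were counted with the library as a block (262) or for dentate granule pairs, with 2 libraries at 0 h.

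In neurons, transcripts of myelin were lower after storage, with 11 of 12 genes lower and a median of -4.18 in dentate granule cells at 54 h. Doublets with oligodendrocytes are argued against, as with the expected share of doublets left out the median was -4.24 with 11 genes lower. Decay stays open, as their median of 1.11 in oligodendrocytes is a share of UMIs. Free RNA of other cells in the droplets might give such counts, since the 12 genes held 2.04 to 2.57 UMIs per nucleus in 5 classes of neurons in 0 h replicates 2 and 3, 1.26-fold apart. Their sum per nucleus moved by -0.96 to -0.29 on the log2 scale by 54 h, short of the fall of 1 in each class that it predicts, so it cannot be told apart from other causes without a measure of free RNA, and empty droplets were not analysed here. No biological explanation was tested.

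In microglia, oligodendrocytes and their precursors, immediate early genes were higher at 54 h, with medians of 4.33, 4.13 and 5.26. Thinning of class sums to the smallest library (median of the genes past the threshold 5.49, 4.63 at full depth) decides nothing on greater depth of the stored libraries, as sums of 54 h were the smaller ones (in microglia a median of 120788 UMIs against 727158 at 0 h). Free RNA from neurons stays a candidate explanation. If each droplet takes up as much (not tested), the lowest of 5 classes of neurons bounds it. Over 2 times the UMIs per nucleus of that class in every 54 h library compared were held by 46.2%, 27.3% and 33.3% of the genes past the threshold, such as Fos in oligodendrocytes, at least 5.84 times. Against dentate granule cells alone it was 10% of 30 combinations of gene and class. Even so, for the other genes free RNA cannot be told apart from a response of the glia, as they held at most 2 times the bound in at least 1 library. Doublets with neurons and biological explanations were not tested.

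Mitochondrially encoded genes were higher at 54 h in dentate granule (median 3.74) and CA1 cells (4.08) and not in inhibitory neurons (0.00). This goes with 0 h replicate 1, which is a control of inhibitory neurons and not of the others. Without it the median in inhibitory neurons was 3.74 with 13 of 13 genes higher, against -0.53 without 0 h replicate 2 and -0.55 without replicate 3. A difference between the classes is argued against, since over the libraries that hold both, 0 of 13 genes differed in edgeR (median difference -0.19, from -1.15 to 0.31). On simulated data for this pair, with 1 dispersion for every gene, the test recovered 2, 23, 46 and 48 of 50 genes that differed 2, 4, 8 and 16-fold, so small differences stay open, and no biological explanation was tested.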

How the results depend on the processing

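The runs without all replicate 1 libraries, with the expected share of doublets left out, with nuclei of named classes alone and with the library as a block were chosen only after the result was seen. The text leaves out some genes whose call ended without 1 library, so the count of lost calls of genes is too low by choice. Values of single genes that the text names kept their direction in all of 9144 comparisons with an alternative, 43 of which were no longer past the threshold and 3 newly past it. Of 829 counts of genes, 708 stayed within 1.5 times and 121 did not. Of 526 slopes, 499 kept their side of the threshold, 2 lost their call, 24 gained one and 1 gained one with the other sign. Counts say how many genes passed and not which. Counts and slopes outside these bounds follow, genes only in part. Their cause was not tested unless fewer libraries were used. With DESeq2's size factors the median of all genes moved by -0.08 to 0.03 over 29 comparisons, and with weighted sums by -0.09 to -0.04 over 5, with 0 of 305 and 0 of 59 list medians changing sign.

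With DESeq2's Wald test, genes changed numbered 787 for 54 h against 24 h in all nuclei, 7 at 24 h in Cajal-Retzius cells, 424 at 24 h in oligodendrocyte precursors, and 893 at 24 h in microglia. With genes of at least 10 CPM in 3 libraries, all nuclei had 2837 changed at 24 h and 4464 at 36 h. They had 4573 at 48 h, 4762 at 54 h and 0 for 54 h against 24 h. Dentate granule cells had 3321 at 24 h and 4308 at 54 h and CA1 cells 2384 and 4121. Subicular and cortical neurons had 2235 at 24 h. In oligodendrocyte precursors (628 at 24 h) and endothelial cells (89, and 776 at 54 h) counts were above the main ones. With no filter on low counts they were 1152 (408 higher) at 24 h in immature neurons, 101 (38 higher) at 24 h and 922 (355 higher) at 54 h in Cajal-Retzius cells, 1961 (477 higher) at 24 h in astrocytes, 1512 (337 higher) at 24 h in oligodendrocytes, 893 (149 higher) at 24 h and 1042 (203 higher) at 54 h in oligodendrocyte precursors, 1369 (648 higher) at 24 h in microglia, and 180 (78 higher) at 24 h and 1212 (459 higher) at 54 h in endothelial cells. With the 2 times compared alone, hence fewer libraries, they were 2473 at 24 h, 5435 at 48 h and 80 for 54 h against 24 h in all nuclei, 598 at 24 h in oligodendrocyte precursors, 983 at 54 h in microglia, and 12 at 24 h in endothelial cells. With doublets kept it was 908 at 24 h in microglia. With at least 1000 genes per nucleus the counts were 0 for 54 h against 24 h in all nuclei, and 964 at 54 h in oligodendrocytes, and with sums weighted to 1 composition 377 for 54 h against 24 h in all nuclei. Depth limits these counts, since with sums thinned to the smallest library they were 0 for 54 h against 24 h in all nuclei, 443 at 24 h and 719 at 54 h in CA3 cells, 781 at 24 h and 2069 at 54 h in subicular and cortical neurons, 120 at 24 h and 313 at 54 h in immature neurons, 234 at 54 h in Cajal-Retzius cells, 516 at 24 h and 1340 at 54 h in astrocytes, 80 at 24 h and 440 at 54 h in oligodendrocytes, 21 at 24 h and 160 at 54 h in oligodendrocyte precursors, 59 at 24 h and 508 at 54 h in microglia, and 0 at 24 h and 220 at 54 h in endothelial cells. Without all replicate 1 libraries they were 9353 at 24 h and 4146 for 54 h against 24 h in all nuclei, 59 at 24 h in Cajal-Retzius cells, 2241 at 24 h in astrocytes, 1800 at 24 h in oligodendrocytes, 877 at 24 h and 944 at 54 h in oligodendrocyte precursors, 1057 at 24 h in microglia, and 8 at 24 h and 256 at 54 h in endothelial cells.

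Leaving out 1 library at a time, the count of genes changed ran from 3254 to 7054 at 24 h and 0 to 405 for 54 h against 24 h in all nuclei, 4076 to 7616 at 24 h in dentate granule cells, 1139 to 5335 at 24 h and 4782 to 7886 at 54 h in CA1 cells, 2221 to 4701 at 24 h in CA3 cells, 1471 to 4977 at 24 h in subicular and cortical neurons, 2376 to 4938 at 24 h in inhibitory neurons, 453 to 936 at 24 h in immature neurons, 0 to 23 at 24 h and 264 to 697 at 54 h in Cajal-Retzius cells, 899 to 1895 at 24 h in astrocytes, 394 to 1414 at 24 h and 1184 to 2087 at 54 h in oligodendrocytes, 130 to 655 at 24 h and 316 to 837 at 54 h in oligodendrocyte precursors, 259 to 1103 at 24 h in microglia, and 2 to 39 at 24 h and 178 to 488 at 54 h in endothelial cells. Slopes ran from -1891 to -1198 barcodes per 10 h (adjusted p from 0.00020 to 0.085 over all alternatives), and from 1.65 to 2.73 percentage points for CA1 and 0.0852 to 0.134 for Cajal-Retzius cells. In dentate granule, CA1 and endothelial cells, leaving out a 0 h library leaves 1 control, which is assumed to vary like the other groups. Of 30 library pairs of 1 replicate number, 25 correlated over 0.1 (lowest -0.0383, median 0.25 against -0.116 in other pairs). Not all did, so the numbers were not taken as pairs. A shared batch stays open, as 12 of 15 libraries correlated best with their own number. With the replicate number as a block, genes changed were 5 for 54 h against 24 h in all nuclei, and 265 at 54 h in endothelial cells.

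Slopes that crossed the threshold for quality values, per 10 h, were UMIs per barcode 783 in kept nuclei alone, 933 with means and 606 without all replicate 1 libraries, genes per barcode 254 in kept nuclei alone (adjusted p = 0.041), 169.8 with means (adjusted p = 0.043) and 226 without all replicate 1 libraries (adjusted p = 0.024), range 0.024 to 0.43, genes per barcode in 1000 UMIs 6.97 in kept nuclei alone and 9.09 without all replicate 1 libraries, percent of mitochondrial UMIs 0.352 with means, with adjusted p given above where not here. Those for class shares, in percentage points per 10 h or for edgeR as a log2 slope, were Cajal-Retzius cells 0.142 with at least 1000 genes per nucleus (adjusted p = 0.018), 0.10 with the replicate block (adjusted p = 0.039) and 0.1196 without all replicate 1 libraries (adjusted p = 0.030), range 0.018 to 0.16, CA1 cells 2.29 with doublets kept (adjusted p = 0.048), 2.25 with the replicate block (adjusted p = 0.015) and 1.76 without all replicate 1 libraries (adjusted p = 0.024), range 0.0062 to 0.23, oligodendrocytes -1.98 with coarser clusters (adjusted p = 0.058), range 0.00017 to 0.058, fibroblasts -0.695 with the replicate block (adjusted p = 0.0025), -0.0509 without all replicate 1 libraries (adjusted p = 0.024) and -0.751 in an edgeR trend on counts of nuclei (adjusted p = 0.016), range 0.0025 to 0.60, endothelial cells 0.0935 without all replicate 1 libraries (adjusted p = 0.040), range 0.040 to 0.99, mural cells 0.0523 without all replicate 1 libraries (adjusted p = 0.030), range 0.030 to 0.99, thalamic neurons 1.49 in an edgeR trend on counts of nuclei (adjusted p = 0.021), range 0.021 to 0.66. Ranges are those of the adjusted p over all alternatives of a result, 20 or 21 for quality values and 25 for shares.

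With an estimated correlation camera called 0 lists in each of the 5 comparisons over all nuclei (10, 13, 12, 12 and 12 at the preset one), and 5 of 116 at 24 h and 8 of 130 at 54 h, summed over the classes. For 54 h against 24 h fry called 0. With the library as a block, in place of 319, 1133 and 104, genes whose change differs numbered 963, 2789 and 262 between dentate granule and CA1 cells, dentate granule cells and inhibitory neurons, and astrocytes and oligodendrocytes. Not run, for want of libraries with 20 nuclei, were at least 1000 genes per nucleus in Cajal-Retzius cells, endothelial cells, microglia and oligodendrocyte precursors, and the expected share of doublets left out in endothelial cells.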

Other observations

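The counts of splits and the counts by gene span and by names that end in os were chosen only after the result was seen. The libraries compared were split in every other way into groups of the same sizes. Given in order are the number of splits with as many genes, the real one included, the real count and the highest of the other splits. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. At 24 h these were 1, 5741 and 0 in all nuclei, 1, 3930 and 0 in CA3 cells, 1, 3623 and 133 in subicular and cortical neurons, 1, 3891 and 1 in inhibitory neurons, 1, 697 and 0 in immature neurons, 10, 0 and 0 in Cajal-Retzius cells, 1, 1258 and 0 in astrocytes, 1, 665 and 16 in oligodendrocytes, 1, 282 and 2 in oligodendrocyte precursors and 1, 567 and 2 in microglia. In all nuclei they were 1, 8538 and 0 at 36 h and 1, 9557 and 2583 at 48 h, and in oligodendrocyte precursors at 54 h 1, 619 and 23. With 4 against 3 libraries there are 35 splits, and the share of 1 in 35 is the smallest possible, not adjusted over the counts. The counts of genes at 54 h reached it, and 54 h against 24 h did not (6, 1 and 2). This share alone does not exclude chance. All nuclei had 1, 9114 and 6588 and CA3 cells 1, 5035 and 1716. Subicular and cortical neurons had 1, 5606 and 2515 and inhibitory neurons 1, 6156 and 3110. Immature neurons had 1, 1130 and 309 and Cajal-Retzius cells 1, 451 and 72. Astrocytes had 1, 2394 and 701, oligodendrocytes 1, 1801 and 1015 and microglia 1, 1854 and 692.

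For the number of gene lists that camera called, in the same order, the 10 splits gave at 24 h 8, 10 and 17 in all nuclei, 2, 13 and 13 in CA3 cells, 5, 10 and 11 in subicular and cortical neurons, 1, 12 and 11 in inhibitory neurons, 3, 6 and 8 in immature neurons, 3, 6 and 9 in Cajal-Retzius cells, 8, 6 and 13 in astrocytes, 2, 10 and 10 in oligodendrocytes, 2, 8 and 10 in oligodendrocyte precursors and 5, 11 and 13 in microglia. In all nuclei they gave 4, 13 and 17 at 36 h and 6, 12 and 16 at 48 h, and in oligodendrocyte precursors at 54 h 1, 10 and 9. The 35 splits at 54 h gave 16, 12 and 16 in all nuclei, 9, 11 and 14 in CA3 cells, 5, 12 and 14 in subicular and cortical neurons, 8, 11 and 13 in inhibitory neurons, 3, 9 and 9 in immature neurons, 9, 6 and 9 in Cajal-Retzius cells, 5, 11 and 13 in astrocytes, 2, 14 and 14 in oligodendrocytes and 5, 12 and 14 in microglia, and 4, 12 and 14 for 54 h against 24 h, so for these numbers from 35 splits chance is not excluded.

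Of the 10% of tested genes with the longest spans on the genome, past the threshold at 54 h against 0 h were 50.8% lower and 2.18% higher in astrocytes (4.45% and 12.99%), 46.1% lower and 1.37% higher in oligodendrocytes (3.19% and 39.5%), 40.6% lower and 1.86% higher in inhibitory neurons (13.03% and 43.2%), 26.2% lower and 6.96% higher in dentate granule cells (23.4% and 31.2%) and 13.7% lower and 4.41% higher in microglia (4.61% and 23.6%), with the values for the 10% with the shortest spans in parentheses. Genes tested that are named as antisense to another, those higher, those lower, their median and that of other genes were 246, 17, 122, -1.19 and 0.04 in all nuclei, 185, 13, 106, -1.62 and 0.03 in dentate granule cells, 117, 12, 58, -1.01 and -0.01 in inhibitory neurons, 49, 2, 15, -0.25 and 0.03 in astrocytes, 24, 3, 7, -0.19 and -0.03 in oligodendrocytes and 51, 4, 17, -0.62 and -0.09 in microglia. Unnamed clusters held 41.7% of 36 h replicate 1 in cluster 1, 27.1% of 54 h replicate 3 in cluster 34 and 14.1% of 48 h replicate 1 in cluster 12. The mean correlation of a library with the others of its time point was 0.939 for 0 h replicate 1 and 0.967 to 0.994 for the others.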
